A study of Mus musculus with 27 samples.

How the data were processed

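The series measured RNA from mouse hippocampus in a 2 by 2 design of surgery and treatment, per the labels. The mice were of the outbred ICR strain and had either a sham operation or ovariectomy (OVX), followed by saline or xanthohumol (Xmo), a prenylated flavonoid of hops. The gene expression part held 15 libraries, with 3 in the sham saline group and 4 in each of the sham Xmo, OVX saline and OVX Xmo groups. The miRNA part held 12 libraries, 3 per group. The labels do not tie a miRNA library to an mRNA library, and nothing states that the replicates are separate animals, so every p-value measures only the spread between samples.

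Hippocampi were flash frozen and RNA was harvested with Trizol, per the labels' protocols. Libraries were made from 1 µg of total RNA with a TruSeq RNA kit, per the labels' protocols. The submitters' processing notes list FastQC 0.11.2, Trimmomatic 0.36, Bowtie2 2.3.2 and StringTie 1.3.3b with the genome build GRCm38.p6, without saying which tool made which column. Whether the counting used strand is not given in the sources used here.

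The deposited gene table held counts for 51826 features, which were whole numbers per sample. It also held TPM and FPKM values that the authors deposited for the same samples, per the file headers. TPM summed to about 1e+06 per sample and was used with FPKM only to check the sample order and the units. The deposited miRNA table held read counts for 1387 mature miRNAs and a further column of counts per sample, named exp in the file headers. The exp values were whole numbers, and 7216 of 7542 values between 1 and 99 reads were equal to the read count (95.7%). At high counts they were a smoothly falling share of the reads, and how they were made is not given in the sources used here. The same table held the authors' log2 fold changes, and DESeq2 p-values and q-values, per the file headers. The fold changes were ratios of the mean exp values, with an exception in miR-532-3p, whose fold changes against sham saline did not match its mean exp values. These deposited p-values and q-values were read only for comparison with the tests run here. A further 12 columns of per-sample values carried names that match no sample of the series and were not used in any step.

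Gene counts summed to between 20.8 and 39.1 × 1e+06 per library, and miRNA reads to between 9.66 and 11 × 1e+06. Intervals and floors derived from counts cover counting error only. Features with low counts were removed with edgeR's filterByExpr by group, which left 19969 genes and 605 miRNAs. Counts were scaled by TMM (trimmed mean of M-values) factors, and every gene or miRNA was fitted with edgeR's quasi-likelihood negative binomial model on all 4 groups, with 11 residual degrees of freedom for genes and 8 for miRNAs. The 5 comparisons per assay were OVX saline against sham saline, OVX Xmo against OVX saline, sham Xmo against sham saline, OVX Xmo against sham saline, and the interaction, which is the Xmo effect in OVX mice minus that in sham mice. A feature passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors of log2 fold changes were derived from the fold change and its F statistic, and log2 values for lists and figures used a prior count of 2. Levels are TMM-scaled CPM (a share of the library, per 1e+06 counts) unless stated to be unscaled, and are given as mean ± SD. For a gene with 0 counts in a whole group, the fold is a lower bound computed at 3 counts per library.

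Gene lists for cell types, regions and pathways (32 for genes, 16 for miRNAs) were tested with camera in limma with its preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The list tests were repeated with the correlation estimated from the data, and without each library in turn. The relation between the ovariectomy and Xmo changes was measured as the Pearson correlation and covariance of log2 fold changes across genes. These comparisons share the OVX saline libraries, so 100 simulated sets without effects gave the values that sharing produces when genes vary independently. Changes that many genes share within a library were absent from these sets, so their SDs and ranges leave out that spread. The OVX saline libraries were also divided between the comparisons. For the interaction, the share of features without overlap expected without effects was taken from simulated counts too. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

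Groups, comparisons, lists, thresholds, the alternatives marked as planned and the rule for naming genes were chosen before the data were examined. By that rule, genes past the test whose groups did not overlap were named by the size of the fold change, at most 10 up and 10 down per comparison (5 and 5 for OVX Xmo against sham saline and for the interaction). Where fewer than 3 passed, the 5 with the smallest p were named and said not to pass. From each list, at most 4 members past the test were named by smallest p. For a list past its own test without such a member, the 2 with the smallest p were given as values. A fixed set of genes and miRNAs with known roles was also written down and is given where it bears on a list.

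Other settings chosen beforehand were relative log expression (RLE) size factors, no filter, DESeq2's Wald test, a model of the compared groups only, the replicate number as a block, an estimated correlation in camera, and leaving out each library in turn. Settings added after the values were seen were scaling without mitochondrial genes and their 5 nuclear copies, leaving out sham saline 2 and 3, leaving out OVX Xmo 2 and sham saline 2, the log2 mitochondrial share as a covariate, leaving out genes whose span was at least 50% covered by another tested gene, and the exp counts for miRNAs. The covariate is itself a measurement of the same libraries.

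The tests were tested on simulated data drawn from the real means and library sizes. With 200 of 19879 genes changed in a simulation of OVX saline against sham saline, edgeR recovered 45.0% of genes at a log2 fold of 1 and 82.0% at 2, with 3 false among 130 calls. DESeq2 recovered 55.0% and 87.0%, with 20 false among 162 calls. In a simulation of miRNAs for OVX Xmo against OVX saline, edgeR recovered 56.7% at a log2 fold of 1 and 90.0% at 2. Libraries of the same group were checked for duplicates, and no such pair was as alike as sampling noise alone would make it. Pairs across groups were not checked in this way.

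Symbols carried by more than 1 feature (91 of them) were kept apart by Ensembl identifier. Targets of the changed miRNAs were not analysed here, because no 3′ UTR sequences were among the sources used. A few list members that the naming rule would give are not reported here.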

Results

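Gene expression was measured by RNA sequencing in 15 hippocampus libraries from ICR mice, and miRNAs were measured in 12 further libraries. The groups were sham saline (n = 3 for genes), sham Xmo, OVX saline and OVX Xmo (n = 4 each), with n = 3 per group for miRNAs. Gene counts summed to 29.6, 28.7 and 29.1 × 1e+06 in sham saline 1 to 3, and to 30.3, 39.1, 27.6 and 37.6 × 1e+06 in sham Xmo 1 to 4. They summed to 39.1, 27.9, 29.0 and 22.6 × 1e+06 in OVX saline 1 to 4, and to 34.8, 33.7, 20.8 and 27.1 × 1e+06 in OVX Xmo 1 to 4. miRNA reads summed to 10.3, 10.6 and 10.2 × 1e+06 in sham saline and 9.66, 9.90 and 10 × 1e+06 in sham Xmo. They summed to 10.4, 10.2 and 11 × 1e+06 in OVX saline and 10.3, 10.1 and 9.86 × 1e+06 in OVX Xmo.

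The sham saline mRNA libraries differed on average from the others before any gene was tested. Protein genes encoded by the mitochondrial genome took 25.8% ± 7.70 of the counts in sham saline (SD, n = 3; 19.0%, 34.1% and 24.2%). They took 16.2% ± 2.08 in sham Xmo, 14.2% ± 1.94 in OVX saline and 14% ± 1.75 in OVX Xmo (SD, n = 4 each). Ribosomal protein genes took 0.486% ± 0.0502 in sham saline, against 0.707% ± 0.0676 in sham Xmo, 0.735% ± 0.0359 in OVX saline and 0.637% ± 0.0753 in OVX Xmo. Single libraries overlapped in both shares. The mitochondrial share of sham saline 1 (19.0%) lay below that of sham Xmo 1 (19.2%). Its ribosomal share (0.543%) lay above that of OVX Xmo 4 (0.536%). The choroid plexus transcript Ttr ranged from 49.3 to 8645 unscaled CPM across the 15 libraries, and from 88.5 to 8645 unscaled CPM within sham Xmo.

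**Figure D1:**
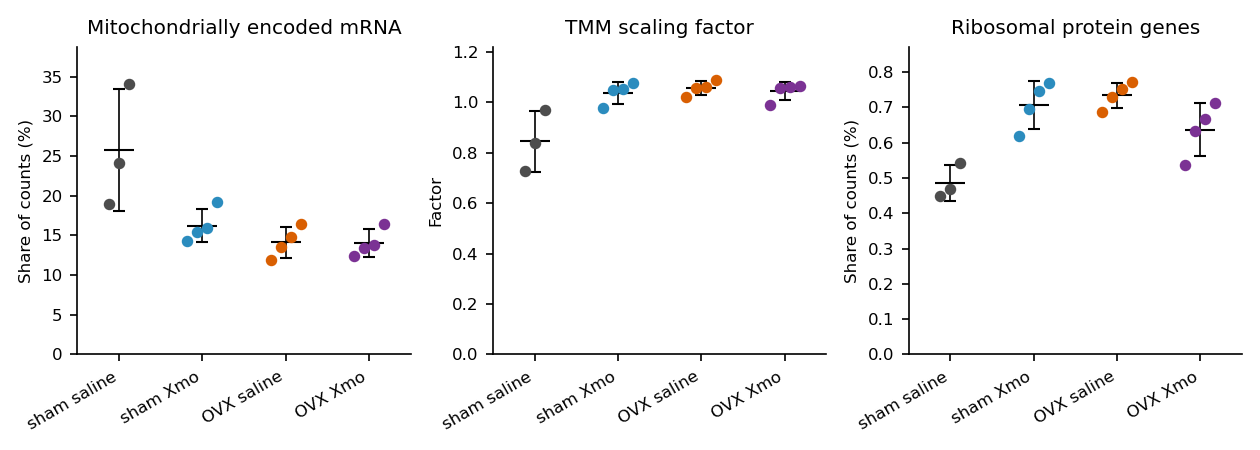
Share of counts from mitochondrially encoded protein genes (%), TMM scaling factor and share of counts from ribosomal protein genes (%) in each of 15 mRNA libraries by group, with mean and SD. Sham saline (n = 3) had the highest mean mitochondrial share (25.8%) and the lowest mean TMM factor (0.845) and ribosomal share (0.486%).

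The comparison of OVX saline with sham saline asked how ovariectomy alone altered the hippocampus. Of 13 mitochondrially encoded genes 10 fell, while 14 of 37 nuclear genes of oxidative phosphorylation and 12 of 41 ribosomal protein genes rose, and 1 of the 37 fell. With an estimated correlation the lists had camera adjusted p = 0.410, 0.410 and 0.581. mt-Nd1, a complex I subunit (ENSMUSG00000064341, MT:2751-3707, GRCm38.p6), fell from 38715 ± 19689 to 11213 ± 2265 CPM (log2 fold change −1.79, SE 0.31; edgeR adjusted p = 0.0132). Sdhb, a subunit of complex II (ENSMUSG00000009863, chromosome 4:140961203-140979193), rose from 72.7 ± 6.08 to 109 ± 7.04 CPM (0.58, SE 0.09; edgeR adjusted p = 0.00945). Rpl8 of the large ribosomal subunit rose from 104 ± 17.4 to 181 ± 6.26 CPM (0.79, SE 0.12; edgeR adjusted p = 0.00945). Vamp2, the synaptic vesicle fusion protein (ENSMUSG00000020894, chromosome 11:69088490-69092384), fell from 971 ± 230 to 591 ± 43.4 CPM (−0.72, SE 0.13; edgeR adjusted p = 0.0138). Every gene named from this comparison as having risen or fallen had values without overlap between the 4 OVX saline and 3 sham saline libraries.

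Of 13 mitochondrially encoded genes, 10 fell and 3 did not pass, and 13 passed when adjusted over the list alone. mt-Nd6 fell by 2.42, mt-Nd4l by 2.06 and mt-Atp8 by 1.85. The list median was −1.47 (camera adjusted p = 1.45e-19, and adjusted p = 0.410 with an estimated correlation). Of 37 nuclear oxidative phosphorylation genes, 14 rose, 1 fell and 22 did not pass, against 22 and 1 over the list alone. The complex IV subunit Cox5a rose by 0.83, the ATP synthase subunit Atp5e by 0.85 and Sdhd by 0.52. The list median was 0.31 (camera adjusted p = 1.49e-10, and adjusted p = 0.410 with an estimated correlation). Of 41 ribosomal protein genes, 12 rose and 29 did not pass, against 19 up and 1 down over the list alone, with Rps14 up by 0.78 and Rplp0 by 0.67. Their median was 0.28 (camera adjusted p = 5.27e-10, and adjusted p = 0.581 with an estimated correlation). The mitochondrial share was 25.8% in sham saline against 14.2% in OVX saline, and the share of ribosomal protein genes 0.486% against 0.735%, so the mitochondrial and ribosomal lists measured the same quantity as these library shares.

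Of 30 genes of synapse and plasticity, 4 fell and 26 did not pass (4 over the list alone), with a median of −0.18 (camera adjusted p = 0.00258, and adjusted p = 0.410 with an estimated correlation). The vesicle protein gene Syn1 fell by 0.86 and the NMDA receptor subunit Grin2b by 0.47, from 1012 ± 119 to 731 ± 44.4 CPM. The neurotrophin Bdnf measured 44.0 ± 4.56 CPM in sham saline and 42.6 ± 6.57 CPM in OVX saline. In the dentate gyrus granule cell list, 1 of 15 rose (1 over the list alone), Il16 by 0.48, with a median of 0.24 (camera adjusted p = 0.0128, and adjusted p = 0.662 with an estimated correlation). The synapse list did not pass without sham saline 3 (camera adjusted p = 0.0703), nor the granule cell list without OVX saline 1 (camera adjusted p = 0.0652).

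Of 20 endothelial genes, 3 fell and 17 did not pass, against 9 over the list alone, with Ly6c1 down by 1.44, the transcription factor Sox17 by 1.20 and the VEGF receptor Flt1 by 0.54. The endothelial median was −0.41 (camera adjusted p = 0.000248, and adjusted p = 0.410 with an estimated correlation). Of 18 inflammation genes, 1 fell, against 3 over the list alone, with a median of −0.39 (camera adjusted p = 0.00897, and adjusted p = 0.410 with an estimated correlation). That gene was Lcn2, an iron-binding acute phase protein, at 37.2 ± 53.2 CPM in sham saline and 0.150 ± 0.175 CPM in OVX saline. Its level in sham saline rested on library 2, with 98.6 CPM against 4.65 and 8.42 CPM in libraries 1 and 3. None of the 22 choroid plexus genes passed in edgeR (0 over the list alone), and all 22 lay lower, with a median of −1.55 (camera adjusted p = 0.000235, and adjusted p = 0.878 with an estimated correlation). The tight junction gene Cldn1 measured −1.64 and the chloride channel gene Clic6 −2.11. Without sham saline 1 the choroid plexus list did not pass (median −0.81, camera adjusted p = 0.0703).

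Glial and endocrine genes passed in lists that did not pass as a whole. Of 21 microglial features, 3 rose (3 over the list alone), the homeostatic marker Tmem119 from 12.9 ± 2.16 to 20.1 ± 1.68 CPM (0.64, SE 0.15), Csf1r by 0.33 and Selplg by 0.61. Of 20 astrocyte genes, 3 rose and 2 fell (7 and 2 over the list alone). Mlc1 rose by 0.49, Fgfr3 by 0.57 and Htra1 by 0.52, while the sodium pump subunit Atp1b2 fell by 0.53. Of 17 genes of estrogen signalling, 2 fell (2 over the list alone), the progesterone receptor Pgr from 22.8 ± 1.58 to 14 ± 1.35 CPM (−0.70, SE 0.15; edgeR adjusted p = 0.0202) and Igf1r by 0.31. The estrogen receptor Esr1 measured 1.64 ± 0.322 CPM in sham saline and 1.79 ± 0.473 CPM in OVX saline. Among genes of the NRF2 oxidative stress response, Taldo1 rose by 0.66 and Sod1 by 0.42, while Cat fell by 0.34 and Gclc by 0.32. Further list members past the test were B2m (−0.66), Acat2 (0.42), Tsc22d3 (0.64), Nr1d1 (−0.68), Bax (0.68), Rgs5 (−0.58), Cdk5 (0.44) and Gsk3b (−0.49).

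Outside the lists, a large change was in Zfyve27, which encodes protrudin, a protein of endosome transport and neurite growth (ENSMUSG00000018820, chromosome 19:42163951-42194590). It rose from 20.3 ± 2.82 to 64.2 ± 4.53 CPM (1.66, SE 0.12; edgeR adjusted p = 4.90e-06) and measured 62.8 ± 6.98 CPM in sham Xmo and 60.4 ± 4.71 CPM in OVX Xmo. This is a step between the 3 sham saline libraries (17.1 to 22.5 CPM) and all 12 others (54.3 to 73.1 CPM), like that of Gdf1, and whether the sham saline libraries were quantified with other settings was not tested, so Zfyve27 is uncertain. The mitotic kinase gene Nek2 rose by 2.06 and the small heat shock gene Hspb3 by 2.08, both from levels under 0.3 CPM. Wnt10b had 0 counts in sham saline and was at least 2.40-fold higher. Nek2 passed in 10 of 17 other settings here and Wnt10b in 6. Both also rose in sham Xmo and OVX Xmo against the same sham saline libraries. An effect of ovariectomy on them cannot be told apart from a difference of those libraries. S100a9 fell by 6.42, Ngp by 5.20 and the chemokine receptor gene Ccr1 by 3.38, where S100a9 and Ngp belong to the blood list, which did not pass camera (adjusted p = 0.135). Retnlg and Fgr had 0 counts in OVX saline and were at least 15.2-fold and 10.3-fold lower, or 5.81-fold and 3.81-fold without sham saline 2. The secreted protein gene Scgb3a1 fell by 4.85 and the membrane ubiquitin ligase gene Rnf24 by 3.97. Sham saline 2 was high in several of these, with 7.54 CPM of Scgb3a1 against 0.524 and 0.739 CPM in sham saline 1 and 3, and 13.2 CPM of Ngp against 0.454 and 2.59 CPM. When it was left out, Scgb3a1 (−2.66), Ngp (−3.38), Ccr1 (−2.99), Retnlg and Fgr did not pass (edgeR adjusted p = 0.0911, 0.149, 0.111, 0.0523 and 0.134), while S100a9 (−5.23) and Lcn2 (−5.30) did (edgeR adjusted p = 0.0328 and 0.0182). Gdf1 rose from 0.108 ± 0.0138 to 43.3 ± 4.71 CPM (edgeR adjusted p = 1.76e-08), but it lies wholly within Cers1, and their unscaled sum was 65.5 ± 15.6 CPM in sham saline and 90.7 ± 13.8 CPM in OVX saline. Gdf1 is therefore uncertain, as are other genes past the test that overlap another gene, namely A430078I02Rik, Gm17641, Gm12260, Gm15953 and Gm14372 (higher) and Gm26899 and Pcdhga2 (lower). Htra1, which lies within Fgfr2, and Nr1d1, which shares 14.5% of its span with Thra, are uncertain for the same reason. Smaller overlaps, from 7.55% to 21.1% of the span, make Syn1, Il16, Cox5a, Sox17, Fgfr3 and mt-Atp8 less certain.

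In all, 1246 genes passed in OVX saline against sham saline (728 up, 518 down), and 1224 of them had values without overlap between the groups. Across all 19969 genes 24.5% had no overlap, against 5.71% by chance. DESeq2 called 2342. The 1246 calls became 186 without sham saline 2, 80 without sham saline 3, 475 without OVX saline 1, 258 without OVX saline 2, 433 without OVX saline 3 and 269 without OVX saline 4. The balance of directions turned to 565 up and 637 down in a model of these groups only and to 28 up and 52 down without sham saline 3. Of the 61 named genes past the test, 26 passed in fewer than 9 of 17 other settings. In OVX Xmo against sham Xmo, a surgery comparison without sham saline libraries, 2 genes passed in edgeR, with 2027 at an unadjusted p under 0.05, and 0 passed in a model of these groups only. They were AC166936.1 (lower) and Gm22133 (higher), which overlap other genes and are uncertain, and they were looked at after the values were seen.

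**Figure D2:**
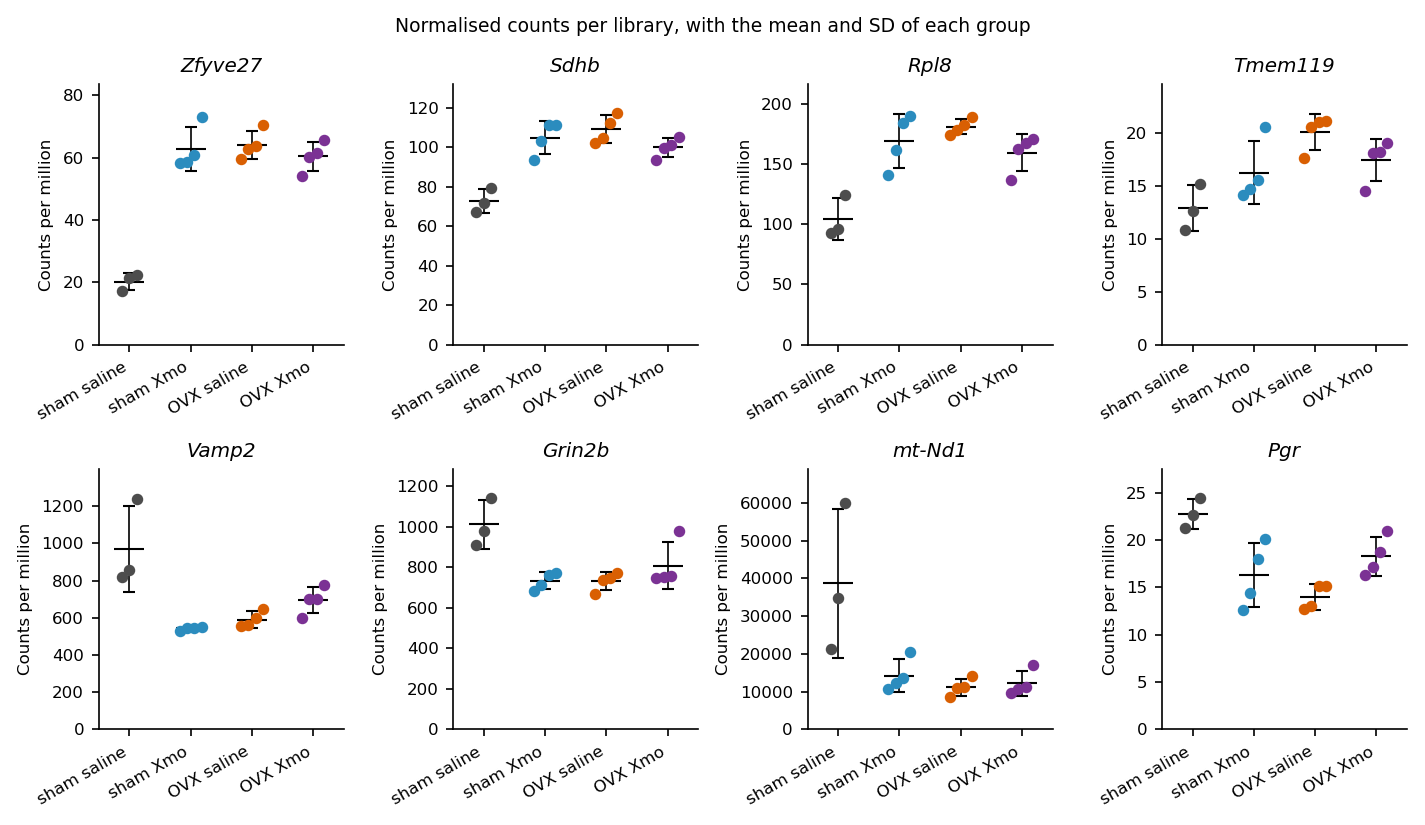
TMM-scaled CPM of Zfyve27, Sdhb, Rpl8, Tmem119, Vamp2, Grin2b, mt-Nd1 and Pgr in each of 15 libraries by group, with mean and SD. Zfyve27 averaged 20.3 CPM in sham saline (n = 3) and between 60.4 and 64.2 CPM in the other groups (n = 4 each).

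The comparison of OVX Xmo with OVX saline asked what xanthohumol did after ovariectomy. No single gene passed in edgeR, with 834 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.301, while DESeq2 called 2. Those with the smallest p, none past edgeR's test, were AC166936.1, Rap1gap2, Cenpa, Gm44597 and Lrrc71. Rap1gap2, a Rap1 GTPase activator (ENSMUSG00000038807, chromosome 11:74383356-74610915), measured 57.3 ± 6.73 CPM in OVX saline and 123 ± 40.7 CPM in OVX Xmo (1.1, SE 0.22). AC166936.1, within Myt1l and so uncertain, measured 4.02 ± 0.0950 and 2.07 ± 0.234 CPM (−0.95, SE 0.15). These were also the 2 genes that DESeq2 called. The centromere histone gene Cenpa measured −0.86, Gm44597 (overlapping Gm43989) −0.87 and Lrrc71 −1.07. Without OVX Xmo 3, 1 gene passed in edgeR, Rap1gap2 (log2 fold change 1.31). Over all genes 3.11% had no overlap between the groups, against 2.86% by chance.

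After Xmo in OVX mice, every list named here had 0 of its members past edgeR's test over all genes, with the number over the list alone also 0 except where given. All 22 choroid plexus genes lay higher (median 1.05, camera adjusted p = 0.000663, and adjusted p = 0.670 with an estimated correlation), with Cldn1 at 1.36 and Clic6 at 1.28. This rested on OVX Xmo 3, with 18.6 CPM of Clic6 against 2.54, 3.65 and 2.57 CPM in the rest of its group, and without that library the median was −0.16 (camera adjusted p = 0.725). Of 20 genes of meninges and fibroblasts, 19 lay higher (median 0.39, camera adjusted p = 6.46e-06, and adjusted p = 0.670 with an estimated correlation), with the forkhead gene Foxc2 at 1.3 and the collagen gene Col1a2 at 0.89. Without OVX Xmo 3 this list did not pass either (median 0.16, camera adjusted p = 0.0544). Of 10 blood genes 9 lay higher (1 past over the list alone; median 0.36, camera adjusted p = 0.00291, and adjusted p = 0.670 with an estimated correlation), with S100a9 at 3.72 and Ngp at 2.23. Of 20 endothelial genes 17 lay higher (1 past over the list alone; median 0.13, camera adjusted p = 0.00291, and adjusted p = 0.670 with an estimated correlation), with Sox17 at 0.87 and Flt1 at 0.20. Of 26 genes of cholesterol and lipid synthesis 24 lay higher (median 0.12, camera adjusted p = 0.000627, and adjusted p = 0.670 with an estimated correlation), with the sterol carrier Stard4 at 0.41 and Insig1 at 0.22.

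The dentate gyrus granule cell list lay lower in 13 of 15 genes (0 past over all genes, 5 over the list alone), with Maml2 at −0.40 and Trpc6 at −0.30. Its median was −0.30 (camera adjusted p = 3.21e-10, and adjusted p = 0.131 with an estimated correlation). Interneuron genes lay higher in 17 of 20, with the GABA synthesis enzymes Gad1 at 0.38 and Gad2 at 0.24 (median 0.16, camera adjusted p = 0.0110, and adjusted p = 0.670 with an estimated correlation). CA1 pyramidal genes lay higher in 11 of 13, with Mpped1 at 1.17 and Dcn at 0.66 (median 0.21, camera adjusted p = 0.0365, and adjusted p = 0.670 with an estimated correlation). Dcn is also a member of the list of meninges and fibroblasts, which lay higher here too. Genes of thalamus and habenula lay higher in 19 of 20, with Synpo2 at 1.05 and Calb2 at 0.56 (median 0.50, camera adjusted p = 0.0475, and adjusted p = 0.670 with an estimated correlation). Here OVX Xmo 2 stood high, with 64.2 CPM of Synpo2 against 2.62, 18.6 and 15.9 CPM, and without it the median was −0.27 (camera adjusted p = 0.397). That list did not pass without OVX saline 1 or 2 either (camera adjusted p = 0.401 and 0.537). Ribosomal protein genes lay lower in 40 of 41, with Rpl14 at −0.24 (median −0.19, camera adjusted p = 1.82e-15, and adjusted p = 0.670 with an estimated correlation). Nuclear oxidative phosphorylation genes lay lower in 36 of 37, with Ndufb2 at −0.19 and Atp5k at −0.27 (median −0.11, camera adjusted p = 2.12e-05, and adjusted p = 0.670 with an estimated correlation). Ependymal genes lay lower in 13 of 15, with Tmem212 at −0.86 and Ccdc153 at −0.62 (median −0.20, camera adjusted p = 0.00856, and adjusted p = 0.670 with an estimated correlation). The CA1 list was lost when any 1 of 5 libraries was left out (camera adjusted p from 0.0675 to 0.235), the ependymal list with any 1 of 4 left out (0.0766 to 0.164) and the interneuron list without OVX Xmo 1 or 3 (0.0594 and 0.109). The mitochondrial shares of these groups were close, at 14.2% ± 1.94 and 14% ± 1.75.

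The comparison of sham Xmo with sham saline asked what xanthohumol did in mice with ovaries. Zfyve27 rose by 1.63 (SE 0.12; edgeR adjusted p = 6.29e-06), by the same step against the sham saline libraries, and is uncertain here too. Casp2, an apoptosis-related protease gene (ENSMUSG00000029863, chromosome 6:42264985-42282508), rose from 3.43 ± 0.606 to 8.08 ± 2.85 CPM (1.23, SE 0.24; edgeR adjusted p = 0.0256). The Wnt ligand Wnt2 rose from 1.86 ± 0.303 to 4.36 ± 1.03 CPM (1.22, SE 0.22; edgeR adjusted p = 0.0197). Trhr, the receptor of thyrotropin-releasing hormone (ENSMUSG00000038760, chromosome 15:44196135-44235912), fell from 3.26 ± 1.47 to 0.812 ± 0.278 CPM (−2.02, SE 0.32; edgeR adjusted p = 0.0174). Nek2 rose by 2.04, 4933407K13Rik by 1.15 and Gm26694 by 1.08, and Wnt10b was at least 2.81-fold higher. Nek2 and Wnt10b, which also rose in OVX saline against these sham saline libraries, each passed in 5 of 17 other settings. Lcn2 fell by 5.54, Scgb3a1 by 4.49 and mt-Nd6 by 1.86, and S100a9 fell by 3.44. With sham saline 2 left out, Lcn2 (−3.04), Scgb3a1 (−2.28) and S100a9 (−2.23) did not pass (edgeR adjusted p = 0.0548, 0.152 and 0.175). Overlapping genes past the test, which are uncertain, were Gdf1, Tgtp1, Rapgef4os2 and Gm26694 (higher) and Pcdhga2, Pcdhgb1 and Gm22133 (lower). Rpl9-ps6 and Gm28439, which fell, are copies of other genes and are also uncertain. Every gene named as having risen or fallen had values without overlap between the 4 sham Xmo and 3 sham saline libraries.

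Energy, ribosome and synapse genes also passed in sham Xmo, against the same 3 sham saline libraries as in the ovariectomy comparison. Of 13 mitochondrially encoded genes 8 fell (12 over the list alone), with mt-Atp8 down by 1.54, mt-Nd1 by 1.44, mt-Nd2 by 1.3 and mt-Nd5 by 1.23. Their median was −1.23 (camera adjusted p = 3.34e-17, and adjusted p = 0.293 with an estimated correlation). Of 37 nuclear oxidative phosphorylation genes 4 rose (20 up and 1 down over the list alone), Sdhb by 0.53, Atp5e by 0.80, Cox5a by 0.67 and Sdhd by 0.45. Their median was 0.26 (camera adjusted p = 1.53e-09, and adjusted p = 0.737 with an estimated correlation). Of 41 ribosomal protein genes 4 rose (17 up and 1 down over the list alone), among them Rpl8 by 0.69, Rps14 by 0.76 and Rplp0 by 0.57. Their median was 0.27 (camera adjusted p = 5.96e-10, and adjusted p = 0.737 with an estimated correlation). Of 30 synapse genes 3 fell (9 over the list alone), Syn1 by 1.17, Vamp2 by 0.84 and the vesicle protein gene Syp by 0.48 (14.5% of its span shared with Gm14703). Their median was −0.29 (camera adjusted p = 5.73e-09, and adjusted p = 0.134 with an estimated correlation). The mitochondrial share was 25.8% in sham saline and 16.2% in sham Xmo, and the ribosomal share 0.486% and 0.707%.

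Of 20 oligodendrocyte genes 1 rose (2 over the list alone), the myelin gene Mog by 0.70 (list median 0.26, camera adjusted p = 0.00626, and adjusted p = 0.737 with an estimated correlation). All 22 choroid plexus genes lay higher without a member past edgeR's test (0 over the list alone), with Calml4 (55.6% of its span shared with Gm10653) at 1.63 and Enpp2 at 1.73. The choroid plexus median was 1.55 (camera adjusted p = 0.00389, and adjusted p = 0.775 with an estimated correlation), and it was 0.45 without sham Xmo 4 and 1.07 without sham saline 3, neither past (camera adjusted p = 0.234 and 0.128). All 15 ependymal genes lay higher, 0 past the test, with the cilium genes Tmem212 at 1.06 and Tekt1 at 0.97 (median 0.81, camera adjusted p = 0.000126, and adjusted p = 0.737 with an estimated correlation). Of 20 endothelial genes 1 fell (1 up and 4 down over the list alone), Flt1 by 0.55 (median −0.29, camera adjusted p = 0.0235, and adjusted p = 0.737 with an estimated correlation). None of 23 immediate early genes passed, with Egr1 at −1.02 and Jun at −0.33 (median −0.26, camera adjusted p = 0.00961, and adjusted p = 0.737 with an estimated correlation). None of 20 interneuron genes passed, with Slc32a1 at −0.54 and Gad2 at −0.34 (median −0.20, camera adjusted p = 0.0446, and adjusted p = 0.737 with an estimated correlation). None of 19 neocortical genes passed, with Hs3st4 at −0.31 and Rorb at −0.86 (median −0.33, camera adjusted p = 0.0285, and adjusted p = 0.737 with an estimated correlation). Without sham Xmo 1 the lists of oligodendrocytes, endothelium, immediate early genes, interneurons and neocortex did not pass (camera adjusted p from 0.103 to 0.149), and all but the endothelial list did not pass without sham saline 3 (0.105 to 0.540). Without sham saline 2 the endothelial list had a median of −0.09 and did not pass (camera adjusted p = 0.144). Members past the test in other lists were Igf1r (−0.40), Atp1b2 (−0.64), Lefty1 (0.81) and Taldo1 (0.64).

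In sham Xmo against sham saline 302 genes passed (144 up, 158 down), 299 of them without overlap. Over all genes 14.2% had no overlap, against 5.71% by chance, and DESeq2 called 1138. The 302 calls became 14 without sham saline 3, 673 without sham Xmo 1, 126 without sham Xmo 2, 27 without sham Xmo 3 and 50 without sham Xmo 4. Their balance moved too, with 50 up and 177 down without sham saline 2, and 10 up and 120 down with the mitochondrial share as a covariate. Of 41 named genes past the test, 24 passed in fewer than 9 of 17 other settings.

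The comparison of OVX Xmo with sham saline asked how far treated ovariectomised mice remained from control mice. Casp2 rose from 3.43 ± 0.606 to 10.6 ± 1.12 CPM (1.62, SE 0.24; edgeR adjusted p = 0.0269), Nek2 rose by 1.99, and Wnt10b was at least 3.07-fold higher. Nek2 and Wnt10b rose in every comparison against sham saline, so a difference of those libraries cannot be told apart. Lcn2 fell by 5.30, Scgb3a1 by 4.05, the oxysterol synthesis gene Ch25h by 3.76 and the immune receptor gene Pirb by 2.73. These 4 rested on sham saline 2, and without it they measured −2.79, −1.86, −1.98 and −1.82, none past edgeR's test (adjusted p = 0.151, 0.330, 0.205 and 0.193). Gdf1 and Gm14372 (higher) and Pcdhga2 (lower) passed but overlap other genes and are uncertain, as is Ch25h, with 24.3% of its span shared. Every gene named as having risen or fallen had values without overlap between the 4 OVX Xmo and 3 sham saline libraries. Of 13 mitochondrially encoded genes 9 fell (13 over the list alone), mt-Atp8 by 1.77, mt-Nd1 by 1.66, mt-Nd2 by 1.53 and mt-Nd5 by 1.39. Their median was −1.43 (camera adjusted p = 3.46e-24, and adjusted p = 0.235 with an estimated correlation). Of 37 nuclear oxidative phosphorylation genes 5 rose (12 up and 1 down over the list alone), with Cox5a up by 0.70, Sdhb by 0.46, Atp5e by 0.69 and Sdhd by 0.46 (median 0.23, camera adjusted p = 1.36e-05, and adjusted p = 0.897 with an estimated correlation). Of 41 ribosomal protein genes Rpl8 rose by 0.61, in a list that did not pass camera (adjusted p = 0.0629). The mitochondrial share was 25.8% in sham saline against 14% in OVX Xmo.

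Further lists past camera in OVX Xmo against sham saline had 0 members past edgeR's test, apart from Lcn2, and depended on single libraries. Cholesterol and lipid synthesis genes lay higher in 22 of 26 (2 past over the list alone), with the mevalonate kinase Mvk at 0.57 and Acat2 at 0.42 (median 0.24, camera adjusted p = 0.000397, and adjusted p = 0.897 with an estimated correlation). Synapse genes (3 of 30 past over the list alone) had a median of −0.13, with Vamp2 at −0.48 (camera adjusted p = 0.0371, and adjusted p = 0.897 with an estimated correlation). Endothelial genes (1 of 20 past over the list alone) had a median of −0.32, with Ly6c1 at −1.29 and Pecam1 at −0.47 (camera adjusted p = 0.0458, and adjusted p = 0.897 with an estimated correlation). In the inflammation list Lcn2 alone of 18 genes fell (3 over the list alone; median −0.25, camera adjusted p = 0.0240, and adjusted p = 0.709 with an estimated correlation). With sham saline 2 left out, the cholesterol (median 0.09), endothelial and inflammation lists did not pass (camera adjusted p = 0.129, 0.129 and 0.0702), nor did the synapse list without sham saline 3 (0.508). Igf1r fell by 0.39, while Taldo1 rose by 0.55 and Cdk5 by 0.38. In all 237 genes passed (149 up, 88 down), 234 of them without overlap between the groups, and over all genes 14.9% had no overlap against 5.71% by chance. DESeq2 called 1127. The 237 calls became 440 without sham saline 1, 16 without sham saline 2, 3 without sham saline 3, 2 without OVX Xmo 1, 2 without OVX Xmo 2, 3 without OVX Xmo 3 and 983 without OVX Xmo 4. Of 22 named genes past the test, 20 passed in fewer than 9 of 17 other settings, all but Gdf1 and Pcdhga2.

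The interaction asked whether the Xmo effect differed between OVX and sham mice. Trhr rose in the interaction by 2.84 (SE 0.44; edgeR adjusted p = 0.0236), from 3.26 to 0.812 CPM with Xmo in sham mice and from 1.76 to 3.13 CPM in OVX mice. The neurokinin receptor gene Tacr3 (ENSMUSG00000028172, chromosome 3:134829007-134934579) rose by 4.40 (SE 0.84; edgeR adjusted p = 0.0410), from 2.81 to 0.844 CPM in sham mice and from 0.284 to 1.84 CPM in OVX mice. Lcn2 rose by 8.02 and S100a9 by 7.16, with −5.54 and −3.44 for Xmo in sham mice and 2.48 and 3.72 in OVX mice. Sham saline 2 was high (Lcn2 98.6 against 4.65 and 8.42 CPM, S100a9 12.1 against 2.06 and 2.75 CPM), and OVX saline was at or near 0 (at most 0.325 and 0.200 CPM). Without sham saline 2 they measured 5.55 and 5.97 and passed (edgeR adjusted p = 0.0253 and 0.0342), but each passed in only 13 of 24 other settings. Tacr3 passed in 11 of 24 (adjusted p up to 0.126), Wnt2 in 9 (up to 0.233), Trhr in 18 and Zfyve27 in 24, and 11 of the 19 named genes in fewer than 12. Zfyve27 fell in the interaction by 1.72 and Wnt2 by 1.52. Usp49 (higher) and Gdf1, AC110091.2 and AC166936.1 (lower) passed but overlap other genes and are uncertain. The interaction contains the sham saline libraries, so a deviation of those libraries enters it with the opposite sign from the comparisons against them.

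Synapse and energy lists passed camera with the preset correlation in the interaction, which contains the sham saline libraries. Of 30 synapse genes 2 rose in the interaction (11 over the list alone), Syn1 by 1.45 and Vamp2 by 1.07 (median 0.35, camera adjusted p = 1.88e-07, and adjusted p = 0.228 with an estimated correlation). Of 37 nuclear oxidative phosphorylation genes 2 fell (19 over the list alone), Sdhb by 0.65 and Atp5e by 0.96 (median −0.41, camera adjusted p = 3.78e-11, and adjusted p = 0.353 with an estimated correlation). Of 41 ribosomal protein genes 3 fell (1 up and 29 down over the list alone), among them Rpl8 by 0.87 and Rps14 by 0.98 (median −0.43, camera adjusted p = 3.51e-17, and adjusted p = 0.353 with an estimated correlation). All 13 mitochondrially encoded genes lay higher, 0 past the test and 9 over the list alone, with mt-Nd6 at 2.20 and mt-Atp8 at 1.62 (median 1.26, camera adjusted p = 4.85e-11, and adjusted p = 0.353 with an estimated correlation). Of 15 granule cell genes 1 fell (7 over the list alone), Maml2 by 0.81 (median −0.49, camera adjusted p = 3.42e-05, and adjusted p = 0.353 with an estimated correlation). Of 10 blood genes 1 rose (3 up and 1 down over the list alone), S100a9 (median 0.15, camera adjusted p = 0.0317, and adjusted p = 0.638 with an estimated correlation). The blood median was −0.39 without sham saline 3 and −0.03 without sham Xmo 2. Taldo1 fell by 0.75. The mitochondrial share, at 25.8% in sham saline, was from 14% to 16.2% in the other groups.

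Further interaction lists passed camera with 0 members past edgeR's test. Immediate early genes had a median of 0.41, with Egr1 at 1.44 and Klf4 at 0.96 (camera adjusted p = 0.00522, and adjusted p = 0.647 with an estimated correlation). Interneuron genes (3 of 20 past over the list alone) had a median of 0.36, with Gad2 at 0.58 and Slc32a1 at 0.86 (camera adjusted p = 0.00522, and adjusted p = 0.426 with an estimated correlation). Endothelial genes (3 of 20 over the list alone) had a median of 0.38, with Flt1 at 0.74 and Sox17 at 1.34 (camera adjusted p = 0.00137, and adjusted p = 0.359 with an estimated correlation). Neocortical genes had a median of 0.50, with Etv1 at 1.17 and Cux2 at 0.74 (camera adjusted p = 0.0317, and adjusted p = 0.638 with an estimated correlation). Oligodendrocyte genes (2 of 20 over the list alone) had a median of −0.37, with Mog at −0.89 and Opalin at −0.67 (camera adjusted p = 0.00523, and adjusted p = 0.647 with an estimated correlation). All 15 ependymal genes lay lower (1 past over the list alone), with Tmem212 at −1.92 and Tekt1 at −1.45 (median −1.11, camera adjusted p = 2.39e-05, and adjusted p = 0.483 with an estimated correlation). The blood list was lost when any 1 of 7 libraries was left out, the neocortical list with any 1 of 6 left out, the immediate early list without sham saline 3 or sham Xmo 1 (camera adjusted p = 0.132 and 0.0556) and the oligodendrocyte list without sham Xmo 1 or OVX Xmo 1 (0.0818 and 0.0833). In no comparison did a gene list pass with an estimated correlation.

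In the interaction 83 genes passed (54 up, 29 down), 82 of them without overlap, where each treated library was set against the mean of its saline group. Over all genes 22.4% had no overlap, against 9.73% (SD 0.199) in simulated counts without effects, and DESeq2 called 845. That SD leaves out changes that many genes share within a library, so the excess does not show an effect by itself. The 83 calls became 255 without sham saline 2, 12 without sham saline 3, 302 without sham Xmo 1, 6 without sham Xmo 3 and 14 without sham Xmo 4. They became 6, 7, 35 and 19 without OVX saline 1, 2, 3 and 4, and 49, 9 and 6 without OVX Xmo 1, 3 and 4.

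**Figure D3:**
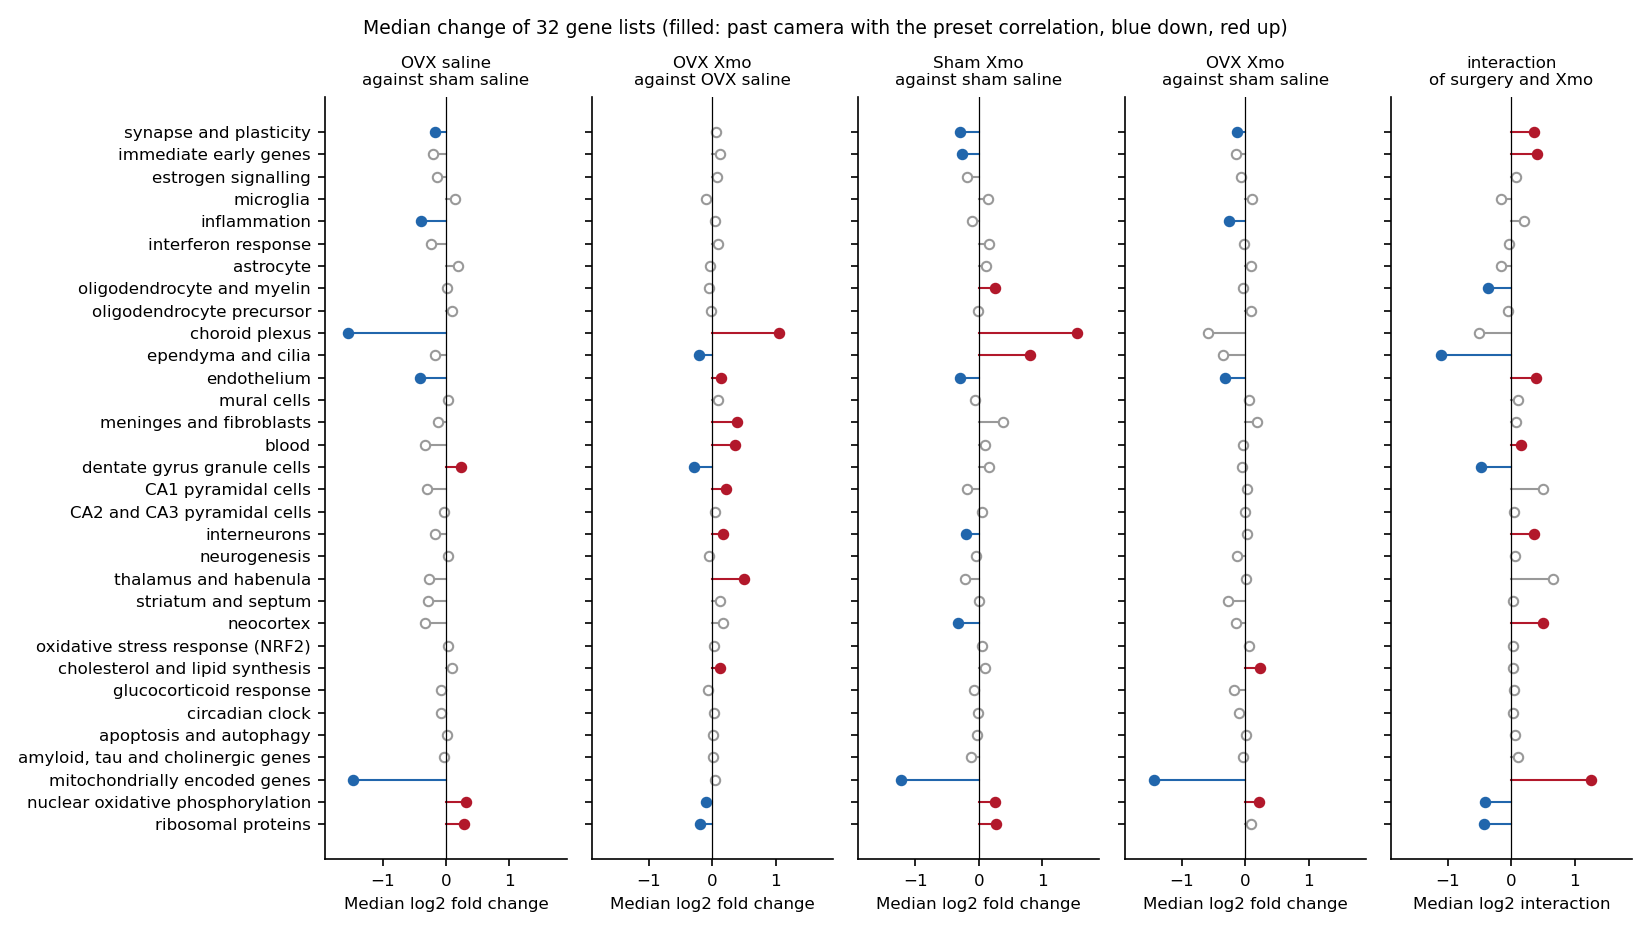
Median log2 fold change of 32 gene lists in 5 comparisons, where filled points passed camera with the preset correlation (red higher, blue lower) and 0 lists passed with an estimated correlation. Mitochondrially encoded genes had medians of −1.47, −1.23 and −1.43 in the comparisons against sham saline and 1.26 in the interaction.

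Whether xanthohumol reversed the ovariectomy changes was measured across all 19969 genes. The log2 fold changes of OVX saline against sham saline and of OVX Xmo against OVX saline correlated at r = −0.477, while simulated data without effects, sharing the OVX saline libraries in the same way, gave r = −0.458 (SD 0.0122; range −0.487 to −0.418). The covariance was −0.0816 against −0.0542 (SD 0.00200) in 100 simulations, a difference of −0.0274. With the OVX saline libraries divided between the comparisons, 6 values averaged r = −0.138 and a covariance of −0.0306 (range −0.0392 to −0.0178). The observed r lay within the simulated range, and the difference in covariance was negative. With sham saline 2 and 3 left out, r was −0.396 and lay outside the simulated range (mean −0.314, SD 0.0104; range −0.339 to −0.289). The simulated genes varied independently, so these ranges leave out changes that many genes share within a library. Neither a value outside them nor the difference in covariance shows a reversal by itself. Across 605 miRNAs r was −0.527, against −0.504 (SD 0.103) in simulated data, with a covariance of −0.105 against −0.0953 (SD 0.0344).

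The miRNA libraries asked the same questions of small RNA. miR-122-5p, a miRNA abundant in liver (encoded on chromosome 18), rose in OVX Xmo from 6.97 ± 0.660 to 70.1 ± 38.9 CPM against OVX saline (3.33, SE 0.38; edgeR adjusted p = 0.00148), higher in 3 of 3 libraries. Its reads were 71, 65 and 81 in OVX saline and 300, 1087 and 739 in OVX Xmo. Against sham saline (8.16 ± 0.328 CPM) it rose in OVX Xmo by 3.10 (SE 0.37; edgeR adjusted p = 0.00261). In sham Xmo it measured 30.8 ± 3.40 CPM, 1.91 above sham saline (SE 0.36), which did not pass in edgeR (adjusted p = 0.0716). miR-412-5p, of the imprinted Dlk1-Dio3 cluster on chromosome 12, fell from 70.5 ± 7.35 CPM in sham saline to 39.2 ± 6.85 CPM in OVX Xmo (−0.85, SE 0.14; edgeR adjusted p = 0.0315), lower in 3 of 3 libraries, but it passed in only 3 of 12 other settings (adjusted p up to 0.332). It was the 1 of 79 measured miRNAs of that cluster past the test (1 over the list alone). It measured −0.77 in OVX Xmo against OVX saline and −0.83 in sham Xmo against sham saline, neither past edgeR's test (adjusted p = 0.0696 and 0.0716).

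Ovariectomy alone left no miRNA past the test in edgeR, with 28 at an unadjusted p under 0.05, while DESeq2 called 1, miR-183-5p. The smallest p belonged to miR-183-5p (2.60), the imprinted miR-127-3p (0.34), let-7a-2-3p (0.72), miR-3097-3p (0.96) and the epithelial miR-200a-3p (0.81), none of which passed in edgeR (adjusted p = 0.485 each). The list of choroid plexus and epithelial miRNAs lay higher in 18 of 20, with 0 past the test and 4 over the list alone (median 0.64, camera adjusted p = 7.36e-08, and adjusted p = 0.752 with an estimated correlation). This rested on OVX saline 3, with miR-183-5p at 28.6, 42.9 and 205 CPM in OVX saline 1 to 3, and without that library the list did not pass (median 0.16, camera adjusted p = 0.239). Choroid plexus mRNAs lay lower in the same comparison, in libraries that the labels do not match to these. The epithelial list was also higher in sham Xmo (median 0.42, camera adjusted p = 0.00920, and adjusted p = 0.780 with an estimated correlation), with miR-211-5p at 1.77, and in OVX Xmo against sham saline (median 0.62, camera adjusted p = 1.31e-05, and adjusted p = 0.783 with an estimated correlation). It was lower in the interaction, with miR-183-5p at −2.37 and miR-200a-3p at −0.82 (median −0.47, camera adjusted p = 0.00632, and adjusted p = 0.839 with an estimated correlation). In sham Xmo it did not pass without sham Xmo 3 (median 0.26, camera adjusted p = 0.508) or sham saline 2 (0.22 and 0.169), nor in the interaction without OVX saline 3 (camera adjusted p = 0.642) or 3 other libraries. No miRNA list passed with an estimated correlation.

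In OVX Xmo against OVX saline miR-122-5p was the 1 miRNA past the test in edgeR, with 46 at an unadjusted p under 0.05, and DESeq2 called 3. Without OVX Xmo 1, 3 miRNAs passed, with miR-155-5p and miR-412-5p added. By smallest p, miR-127-3p measured −0.41, miR-135a-5p 0.56 and the immune miR-155-5p 0.98, none past the test. In OVX Xmo against sham saline 2 miRNAs passed in edgeR and 2 in DESeq2, and without any 1 of sham saline 1, 2 or 3 or of OVX Xmo 2 or 3 the count was 1. The next by smallest p there, not past the test, were miR-3099-5p (−1.45), let-7f-2-3p (1.09) and miR-135a-5p (0.55). In sham Xmo against sham saline 0 passed in edgeR, 57 had an unadjusted p under 0.05, and DESeq2 called 5. In the interaction 0 passed in edgeR and 0 in DESeq2, with 42 at an unadjusted p under 0.05. Its smallest p belonged to miR-6899-3p (−1.31), miR-155-5p (1.27), miR-223-3p (1.84), miR-1249-3p (0.93) and miR-3965 (2.01), and without OVX Xmo 1 miR-122-5p passed (1.75). miRNAs without overlap between groups made up 12.1%, 15.4%, 14.2% and 11.6% of all in the first 4 comparisons in the order of the gene comparisons, against 10% by chance, and 23.3% in the interaction, against 20.3% (SD 1.78) in simulated counts without effects.

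The authors' deposited q-values called 2 miRNAs in OVX Xmo against OVX saline, 9 in sham Xmo against sham saline, 5 in OVX Xmo against sham saline and 0 in OVX saline against sham saline. miR-122-5p was among them in all 3 Xmo comparisons, with deposited log2 fold changes of 3.29, 1.88 and 3.07. The other deposited call in OVX Xmo against OVX saline was miR-532-3p (−6.02), with 166, 234 and 122 reads in OVX saline and 2, 3 and 3 in OVX Xmo, and exp values within 1 of these. In edgeR on all groups it measured −5.94 and did not pass (adjusted p = 0.49), while it passed in a model of these groups only (−5.92, adjusted p = 0.00116) and with exp counts (−5.93, adjusted p = 4.53e-06). Only in sham mice did its exp values and reads disagree by more than 1. Sham saline 3 had an exp value of 241 where 2 reads were counted, and sham Xmo 1 had 2 where 241 reads were counted. The deposited log2 fold changes against sham saline were −0.84 in sham Xmo, 0.25 in OVX saline and −5.77 in OVX Xmo. They go with the mean reads (146 in sham saline, then 81.7, 174 and 2.67), not with the mean exp values (225, then 1.67, 173 and 2.67). This argues against the 2 exp values as tabulated, and for an exchange of them between these libraries. The pass with exp counts on all groups used those values, while the reads keep the wide spread in sham mice.

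**Figure D4:**
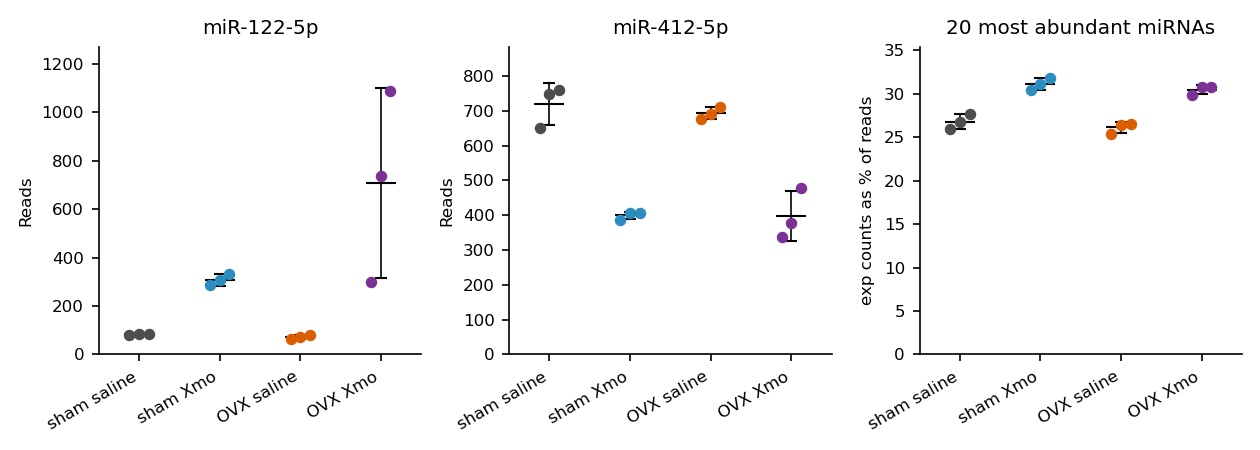
Reads of miR-122-5p and of miR-412-5p, and exp counts as a percent of reads over the 20 most abundant miRNAs, in each of 12 miRNA libraries by group, with mean and SD (n = 3 each). The percent averaged 31.1 in sham Xmo and 30.5 in OVX Xmo, against 26.8 in sham saline and 26.1 in OVX saline.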

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

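The tests of a male animal, of Tsix, of blood in sham mice, of the surgery difference in treated mice and of a batch shared by the Xmo miRNA libraries were chosen only after the result was seen, as were the settings described in processing as added.

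The gene calls in OVX saline against sham saline, the 1 comparison tested for this, went together with the mitochondrial share of the RNA. Over the 12 libraries outside sham saline, 81.2% of 1221 called genes followed the mitochondrial share in the direction of their call, against 61.5% of the other genes, and 39 of 1000 reorderings of the shares within groups reached as high a percent. A candidate explanation for many of these calls is therefore whatever set the mitochondrial share of the sham saline libraries, whether RNA quality, dissection or physiology. Which of these it was, or whether the sham saline libraries were quantified with other settings, was not tested. Called genes were covered by another tested gene 0.629 times as often as other genes, so read assignment between overlapping genes does not explain the calls as a set. When mitochondrial genes and their nuclear copies were left out, 1196 genes passed. TMM scaling of the main fit already allows for a few very abundant genes, so this count was close to set in advance and decides little. An effect of ovariectomy stays open and cannot be told apart, since in OVX Xmo against sham Xmo, without sham saline libraries, 54.7% of the 1246 called genes had the same sign, against 53.3% of all genes (30 of 70 splits reached as high), and those called higher and lower had medians of 0.02 and −0.02, against 0.53 and −0.70 in saline mice.

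Regrouping the samples tested whether chance alone gave as many calls. For OVX saline against sham saline 1 of 35 splits, the real one, reached the count of 1246, with a highest other count of 2. That is the smallest share that 35 splits allow. A chance division of these libraries is therefore unlikely to give as many calls, but it is not excluded. For OVX Xmo against OVX saline the real count was 0, which all 35 splits reach whatever their values (highest other 3), so the splits cannot tell. For sham Xmo against sham saline 1 of 35 splits reached the real 302, but the split that put sham Xmo 1 with sham saline called 296, so chance cannot be excluded. For OVX Xmo against sham saline 2 of 35 splits reached the real 237, so chance cannot be excluded. The split that put OVX Xmo 4 with sham saline called 670, which points to a structure of the samples. OVX Xmo 4 and sham Xmo 1 had the highest mitochondrial shares of their groups (16.5% and 19.2%). They also had the lowest ribosomal shares (0.536% and 0.618%), so in both shares they were the nearest of their groups to the sham saline means. The cause of this structure was not tested. For the interaction 1 of 100 splits reached the real 83, with a highest other of 48. Those splits exchanged saline and Xmo within each surgery group, so they removed any Xmo difference as well as the interaction. A chance division of the treatments is unlikely to give as many calls, but it is not excluded. The splits cannot tell whether the calls come from the interaction itself. For miRNAs the 10 splits of 6 libraries are too few for a share under 0.05. The real counts and highest others were 0 and 0 for OVX saline against sham saline (10 of 10 splits), 1 and 0 for OVX Xmo against OVX saline (1 of 10), 0 and 1 for sham Xmo against sham saline (10 of 10), and 2 and 0 for OVX Xmo against sham saline (1 of 10). The miRNA interaction had a real count of 0 as well, which all 100 splits reach (highest other 4). Where the real count was 0 the splits say nothing on chance.

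miR-122-5p was higher in the Xmo libraries, and the exp column drew attention because it separated the treatments. The exp counts were 31.1% of the reads over the 20 most abundant miRNAs in sham Xmo and 30.5% in OVX Xmo, above the 26.8% and 26.1% of the saline groups. The lowest Xmo library was at 29.9% and the highest saline library at 27.6%, so a library or sequencing batch shared by the Xmo libraries cannot be told apart from the treatment, which it matches library by library, for miR-122-5p or for miR-412-5p. A larger amount of red cells left in the tissue is argued against in OVX mice, where the red cell miRNA with the largest change, miR-144-3p, was 0.24 higher. It cannot be told apart in sham mice, where miR-144-3p was 0.70 higher and miR-451a measured −0.08. Red cell miRNAs cannot show whether the same amount of blood carried more miR-122-5p, so a blood origin stays open in both. Liver RNA in the samples cannot be told apart either, because miR-194-5p, at −0.50 in sham Xmo, has a high level in the hippocampus that would hide a small share, and an effect of Xmo on miR-122-5p itself also stays open, untested.

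The Xmo effect differed between OVX and sham mice by the interaction test for 83 genes, and for 12 lists by camera with the preset correlation, of which 0 passed with an estimated correlation (smallest adjusted p = 0.228). The named genes were Tacr3 (4.40), Usp49 (3.31), Trhr (2.84), Gdf1 (−8.19, a fitted value from 2 to 3 counts per sham saline library), AC110091.2 (−1.87), Zfyve27 (−1.72), Wnt2 (−1.52) and AC166936.1 (−1.39). Zfyve27, Wnt2 and Gdf1 had close means in sham Xmo, OVX saline and OVX Xmo, so their interaction rested on sham saline. Tacr3 and Trhr had opposite differences with Xmo in the surgery groups.

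Some libraries stood apart within their group of 4 by Dixon's test, which marks about 1 in 20 groups by chance. For library measures 4 of 33 groups had such a library (12.1%). Sham Xmo 4 had the highest haemoglobin share (0.525% of counts), OVX Xmo 4 the lowest TMM factor (0.990), and Ttr was highest in OVX saline 4 (454 unscaled CPM) and in OVX Xmo 3 (1748 unscaled CPM). For named genes 23 of 393 groups had one (5.85%), close to the chance rate. In sham Xmo, high values were Gm26899 in library 4 (0.619 CPM), Ly6c1 in 4 (44.3), Rgs5 in 1 (171), Tmem212 in 2 (5.16), Casp2 in 3 (12.3), Pcdhgb1 in 4 (10.7) and Egr1 in 4 (79.8). Low values there were Pcdhga2 in 1 (3.96), Cenpa in 2 (2.17) and Lefty1 in 1 (5.66). In OVX saline, S100a9 in 1 (0.200) and Rplp0 in 4 (237) were high, and Gm17641 in 4 (1.06), Tmem119 in 1 (17.6) and Gfap in 1 (391) were low. In OVX Xmo, Grin2b in 4 (981), Tekt1 in 3 (3.40) and mt-Nd5 in 4 (14613) were high, while Htra1 in 4 (89.3), AC166936.1 in 3 (1.72), Rap1gap2 in 3 (62.9), Gm22133 in 3 (0.0454) and Tacr3 in 2 (0.814) were low.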

How the results depend on the processing

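All settings other than those planned were chosen only after the result was seen, namely the tests without mitochondrial genes, with sham saline 2 and 3 or OVX Xmo 2 and sham saline 2 left out, with the mitochondrial share as a covariate, without overlapping genes and on exp counts. For OVX saline against sham saline the 1246 genes became 568 without a filter, 2342 with DESeq2 (1208 shared), 129 without OVX Xmo 2 and sham saline 2 (99 shared), 19 without sham saline 2 and 3 (9 shared) and 5 with the covariate (5 shared). Leaving out 1 library gave from 80 (sham saline 3) to 978 (sham saline 1). Of 61 named genes past the test, 3 passed with the covariate, Gdf1, Zfyve27 and Pcdhga2, and 59 with RLE factors. For OVX Xmo against OVX saline the 0 genes became 2 with DESeq2, 1 in a model of these groups only, 1 without OVX Xmo 2 and sham saline 2, and 0 to 1 without 1 library. For sham Xmo against sham saline the 302 became 108 without a filter, 1138 with DESeq2, 6 in a model of these groups only, 25 without sham saline 2 and 3 (11 shared) and 130 with the covariate (52 shared), and from 14 (sham saline 3) to 673 (sham Xmo 1) without 1 library. For OVX Xmo against sham saline the 237 became 56, 1127 and 4 in these first 3 settings, 20 without sham saline 2 and 3 (6 shared), 6 without OVX Xmo 2 and sham saline 2, and 3 with the covariate, and from 2 (OVX Xmo 1 or OVX Xmo 2) to 983 (OVX Xmo 4) without 1 library. In that comparison mt-Nd2 changed sign with the covariate, from −1.53 to 0.01. For the interaction the 83 became 20 without a filter, 845 with DESeq2, 28 without sham saline 2 and 3 (13 shared), 277 without OVX Xmo 2 and sham saline 2 (71 shared) and 149 with the covariate (35 shared), and from 6 (sham Xmo 3, OVX saline 1 or OVX Xmo 4) to 302 (sham Xmo 1) without 1 library. Directions changed as well, from 728 up and 518 down in OVX saline against sham saline to 565 and 637 in a model of these groups only (818 shared), 58 and 71 without OVX Xmo 2 and sham saline 2, 28 and 52 without sham saline 3 and 234 and 241 without OVX saline 1, from 144 up and 158 down in sham Xmo to 10 and 120 with the covariate, 7 and 30 with a replicate block and 50 and 177 without sham saline 2, and from 54 and 29 in the interaction to 132 and 17 with the covariate. With sham saline 2 and 3 left out, the lone sample is assumed to vary like the other groups. Zfyve27 passed in all 17 settings in OVX saline against sham saline, with log2 fold changes from 1.3 to 1.74 and adjusted p from 3.65e-39 to 0.00380, but these settings would not remove a difference in how the sham saline libraries were quantified. The cause of these differences in counts was not tested. For miRNAs, OVX saline against sham saline went from 0 to 1 with DESeq2 and stayed at 0 without any 1 library. OVX Xmo against OVX saline went from 1 to 3 with DESeq2 and to 4 with exp counts, and from 1 to 3 without 1 library. miR-122-5p passed there in 11 of 12 settings (log2 fold change 2.88 to 3.68; adjusted p 1.82e-16 to 0.0586), not in a model of these groups only, which called miR-532-3p. In OVX Xmo against sham saline it passed in 11 of 12 and miR-412-5p in 3 of 12 (log2 fold change −1 to −0.73; adjusted p 0.000231 to 0.332). Sham Xmo against sham saline went from 0 to 1 without a filter, 5 with DESeq2, 2 in a model of these groups only and 4 with exp counts, and 0 without any 1 library. OVX Xmo against sham saline went from 2 to 1 with RLE factors, 1 without a filter and 0 in a model of these groups only, and from 1 to 2 without 1 library. The miRNA interaction gave 0 to 1 without 1 library. With an estimated correlation in camera, the gene lists past the test went from 8, 12, 11, 6 and 12 to 0 in each comparison, with smallest adjusted p of 0.410, 0.131, 0.134, 0.235 and 0.228, and the miRNA lists from 1, 1, 1 and 1 to 0. Without sham saline 2 and 3 they went to 14, 14, 10, 6 and 18 (8, 12, 8, 2 and 12 shared). Lost then were cholesterol (adjusted p = 0.475), synapse (0.227), endothelium (0.0600) and inflammation (0.0623) in OVX Xmo against sham saline, and choroid plexus (0.645), oligodendrocytes (0.0988) and endothelium (0.0619) in sham Xmo. Leaving out 1 library gave 8 to 17, 10 to 17, 7 to 15, 5 to 10 and 9 to 17 gene lists, and 3 of 8, 6 of 12, 6 of 11, 4 of 6 and 4 of 12 lists were lost at least once. The miRNA lists ranged over 0 to 1, 0 to 2, 0 to 1, 1 to 2 and 0 to 4. With exp counts the miRNA lists went from 0 to 1 in OVX Xmo against OVX saline and from 1 to 2 in the interaction. The correlation of the ovariectomy and Xmo changes went from −0.477 to −0.396 without sham saline 2 and 3. Simulated data of that design, in which genes varied independently, gave −0.314 (SD 0.0104; range −0.339 to −0.289). The replicate numbers do not pair the samples, since over 21 pairs of mRNA libraries with the same number 2 had a correlation above 0.1 (range −0.215 to 0.186), over 18 miRNA pairs 5 did, and 2 of 15 and 3 of 12 libraries correlated best with their own number. With a replicate block the counts were 178, 0, 37, 2 and 11 for the gene comparisons in this order and 0, 1, 0, 1 and 0 for miRNAs. Depth limits the genes near the filter, and at a log2 fold of 1 the simulated test of OVX saline against sham saline recovered 45.0%. The pseudocount alternatives written for normalised values were not run because the tables hold counts, and the interaction has no model of the compared groups only.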

Other observations

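The test of a male animal and that of Tsix were chosen only after the result was seen, and the values per library described here were noticed in the data. Several transcripts differed in steps between libraries, some within a group and some between groups. The ubiquitin ligase gene Rnf24 measured 50.8, 53.7 and 52.7 CPM in sham saline and between 2.93 and 3.82 CPM in OVX saline. In sham Xmo it measured 50.8, 44.5, 16.5 and 5.35 CPM, and in OVX Xmo 5.67, 39.2, 2.09 and 23.1 CPM. The complex V transcript mt-Atp6 measured 2003 unscaled CPM in OVX saline 4 and 2222 in OVX Xmo 1, against 9051 to 21873 elsewhere. Gm22133, which lies within the ferritin gene Ftl1, measured 0.0294 ± 0.00562 CPM in sham Xmo and 29.0 ± 3.17 CPM in OVX saline. Gdf1 differed between groups, with 2 to 3 counts in each sham saline library, and so did Zfyve27, with 17.1 to 22.5 CPM in sham saline and 54.3 to 73.1 CPM in every other library. Whether the sham saline libraries were quantified with other settings or annotation was not tested. The cause of these steps was not tested.

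Protocadherin transcripts also varied inside a group. Pcdhga2 measured 175, 20.6 and 9.24 CPM in sham saline and between 3.96 and 8.20 CPM in every other library. Acute phase and neutrophil genes varied together there, with Lcn2 at 98.6 CPM, Ngp at 13.2 CPM and S100a9 at 12.1 CPM in sham saline 2, above both other libraries of that group. miR-669c-5p had 0 reads in all 3 sham Xmo libraries and in OVX Xmo 1, 3 reads in OVX saline 1, and between 153 and 234 reads in the others. Whether variants of the outbred strain removed reads from single animals was not tested.

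OVX Xmo 2 had almost no Xist, the RNA that coats the inactive X chromosome, at 0.386 unscaled CPM against 831 to 1372 in the other 14 libraries. A male animal is argued against, since 4 Y-linked genes summed to 0 CPM, and so is assignment of Xist reads to the antisense gene Tsix, which measured 0.682 CPM. The 6 X-linked genes known to escape inactivation that had not been looked at before had a median of −0.31 against the other libraries. They ran from −0.73 (5530601H04Rik) to −0.02 (Kdm5c). The lowest other library was OVX saline 3, at −0.22 with 959 unscaled CPM of Xist. In OVX Xmo 2, 672 other X-linked genes had a median of −0.04. A candidate explanation, resting on few genes and a small margin, is therefore a single X chromosome in that sample. No biological explanation from the design was tested, since the library is 1 of 4 treated alike.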
